A study of Arabidopsis thaliana with 21 samples.

How the data were processed

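Total RNA from above-ground parts of 20-day-old Arabidopsis thaliana plants (Col-0, wild type) was measured on Agilent 1-colour arrays with Cy3, in 7 groups of 3 arrays: no treatment, 300 mM salt, 150 mM salt, 400 mM mannitol, 200 mM mannitol, heat, and combined stress. Per the labels, plants spent 10 days on agar medium with 1% sucrose and 10 days in soil at 23 °C with 16 h of light, and the salt or mannitol solution was fed for 16 h and heat of 35 °C given for 4 h. The combined group received 150 mM salt, 200 mM mannitol and heat, per the labels. Per the labels, the 16 h of feeding began with 1 h of light and ended with 7 h of light after the night, and heat was given in the light. The time of day at which the heat and control plants were harvested, and whether the controls were watered alongside each treatment, are not given in the sources used here. The labels number the replicates 1 to 3 and call them biological, without saying whether plants of a number were grown together, so each p value measures the spread between these samples.

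The authors labelled 1 µg of RNA per array, per the labels, and read the scans with Agilent Feature Extraction 9.1.3.1, per the file headers. The deposited signal values were made by the authors with that program, which subtracted background and detrended each array, per the file headers. The unit of the deposited signal values is intensity. The authors' value table is linear, and each of its columns equals the processed intensity divided by a constant shared within a group, from 785.46 (heat) to 1077 (control), to within 0.0119%, found here from the values. What the constants stand for is not given in the sources used here. All value columns belonged to arrays used here.

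Each array held 45220 spots, 1417 of them controls. The 43803 other spots stood for 43603 probes, 50 of them with 5 spots, which were averaged. RefSeq accessions in the array annotation were matched to transcripts of the TAIR10.1 assembly, with no use of coordinates. In this way 34185 probes were given to 25347 loci, and 9418 probes had no locus and were left out of the gene tests. Loci without a symbol are printed as locus names. For a gene with several probes the brightest probe stood for it, and disagreement of its other probes is stated for named genes. A gene was tested where its probe was well above background (scanner flag) on all 3 arrays of at least 1 group, which left 21860 genes, 6336 of them with several probes and 9040 with a symbol. Spots with an outlier flag (127 over all arrays) were set to missing, and 9 saturated spots were kept.

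Log2 processed intensity minus the 75th percentile of the non-control spots of each array was fitted with 1 mean per group in limma (moderated t tests, Benjamini-Hochberg adjusted p under 0.05, residual degrees of freedom 14, prior 1.84). The comparisons were each treatment with control, the doses with each other, and salt with mannitol at the lower and the higher doses. These doses differ in mM between the solutes. Combined stress was compared with each of its parts, and the departure of the combined response from the sum of its 3 parts was tested. The departure is combined stress minus 150 mM salt minus 200 mM mannitol minus heat plus control counted 2 times, so its standard error is larger (median 0.187 against 0.093 log2). The comparisons, gene lists, rule for named genes, alternatives and thresholds were fixed before the data were examined, apart from those named as added.

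Genes named as largest rises or falls had a symbol, an adjusted p under 0.05 and no overlap between the groups (not asked of the departure). Their signal was well above background on all 3 arrays of the higher group. The rule took the 6 largest rises and 6 largest falls per treatment against control and 4 and 4 in other comparisons. From each list with at least 3 called members or a camera call it also took up to 4 called members with the largest change. These needed no symbol. A panel of 12 genes could be named in any comparison, whether called or not. The rule gave 1585 pairs of gene and comparison, and the text names fewer from the top of each ranking. Where no array of the lower group was well above background, a fold is given as "at least", with each dim array of the lower group set to at least the lowest signal that was well above background on that array.

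The 32 lists hold 580 loci, 565 of them measured: heat shock proteins, heat shock factors, unfolded protein response, late embryogenesis abundant and dehydrin genes, ABA signalling, ABA receptors, ABA synthesis, DREB and CBF factors, proline, galactinol, ion transport, aquaporins, light-harvesting complex, photosystem subunits, Calvin cycle, chlorophyll synthesis, senescence, dark-induced genes, reactive oxygen, jasmonate, salicylate, ethylene, auxin, cell wall, cell division, flavonoids, glucosinolates, clock, root markers, flower and seed markers, reference genes and ribosomal proteins. The last list was drawn by a name pattern and includes some plastid proteins. Lists were tested with camera at a preset correlation of 0.01, adjusted over 448 tests, with an estimated correlation and fry beside it. Of 198 camera calls (129 up, 69 down) none passed with an estimated correlation.

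Alternatives were normexp background correction (offset 50), quantile, median and reference gene scaling, the authors' values, no filter on dim probes, array weights, only the arrays of the groups compared, the replicate number as a block, stricter thresholds, the mean of the probes, and each array left out. Normexp used median spot signals, as the files hold no mean signal. Slide as a fixed block, a single slide, the 2-fold count of genes well above background on every array, further scalings of the shared responses, and the authors' values and strict filter for the lists were added after the data were seen. Shared responses were compared with 20 simulated series of unchanged groups that shared simulated controls, drawn with each gene's pooled spread. The fit was tested on simulated data: heat against control recovered 64.2%, 83.6% and 90.9% of genes changed 1.5-, 2- and 4-fold. The departure recovered 28.4%, 56.7% and 87.9%. Only 67, 67 and 66 of 21789 genes were changed at these folds, far fewer than passed in the real data. The shares therefore do not carry over to the real fits.

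Of the spots of an array 77.23% to 83.84% were well above background, and the 75th percentile lay between 2005.27 and 3173.5 intensity units. Signal over background limits the dim genes, and 3 arrays per group limit the precision. The arrays lay on 6 slides: control, 150 mM salt and 300 mM salt each had 1 of their own, 200 mM mannitol shared 1 with 400 mM mannitol, 400 mM mannitol shared 1 with heat, and heat shared 1 with combined stress. Computation used R 4.3.3, limma 3.58.1, data.table version 1.17.8 and jsonlite 2.0.0, and figures Python 3.11.15 and matplotlib 3.10.9.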

Results

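Plants fed 300 mM salt for 16 h raised genes of dehydration protection and of the abscisic acid (ABA) and jasmonate pathways in their above-ground parts, and lowered ABA receptor, ribosomal protein and cell division genes. Among the largest rises (log2 fold change ± standard error, n = 3 arrays per group) were those of LEA7, a late embryogenesis abundant protein gene (8.89 ± 1.03), BSMT1, which methylates benzoate and salicylate (at least 72.7-fold), the lipid transfer protein gene LTP4 (7.87 ± 0.57), LEA4-5 (7.28 ± 0.63), the redox-responsive factor gene RRTF1 (at least 97.4-fold) and UGT76E12, a glucosyltransferase gene (7.16 ± 0.88). LEA4-5 and UGT76E12 were well above background on 2 of the 3 control arrays, and LEA7 had a standard deviation of 2.65 log2 over the control arrays. "At least" stands where a probe was not well above background on any array of 1 group, and the fold then holds for the main background handling, while several such falls turned direction with normexp. Among the largest falls were those of the ABA receptor gene PYL6 (-4.20 ± 0.23), the receptor kinase gene CRK30 (-4.02 ± 0.37, well above background on 1 of 3 salt arrays), the defensin gene PDF1.2 (-2.89 ± 0.49), the nitrate transporter gene NRT2.3 (-2.81 ± 0.59, 1 of 3 salt arrays), MEE3, a gene of the MYB family (-2.71 ± 0.22), and the auxin transporter gene ABCB21 (-2.47 ± 0.10).

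All 20 measured members of the list of late embryogenesis abundant, dehydrin and cold- or ABA-responsive genes rose in 300 mM salt (20 adjusted over the list alone), among them EM1 (at least 32.6-fold), LTI65 (4.82 ± 0.61) and LTI78 (3.48 ± 0.20). The camera test against all other genes gave adjusted p = 1.03e-12, and adjusted p = 0.242 with an estimated correlation. Of the ABA signalling phosphatases and transcription factors 16 of 16 rose (16 adjusted over the list alone), including the phosphatase genes HAI1 (5.66 ± 0.33) and HAI2 (5.13 ± 0.37) and the ABI5-binding protein gene AFP1 (4.91 ± 0.30), with adjusted p = 1.99e-10, and adjusted p = 0.347 with an estimated correlation. The ABA receptors went the other way: 7 of 9 fell and 2 rose (7 and 2 adjusted over the list alone, adjusted p = 0.0183, and adjusted p = 0.508 with an estimated correlation). PYL4 changed by -2.33 ± 0.16. Of 9 measured DREB and CBF factor genes, which switch on dehydration and cold genes, 8 rose (8 adjusted over the list alone), such as CBF4 (6.26 ± 0.57, 2 of 3 control arrays), DDF1 (at least 20.4-fold) and DREB2A (3.64 ± 0.31), with adjusted p = 7.92e-05, and adjusted p = 0.366 with an estimated correlation. Of the genes of ABA synthesis, breakdown and transport 7 of 12 rose (7 adjusted over the list alone), among them NCED3, the gene of a limiting step (2.33 ± 0.32, adjusted p = 0.0251 for the list, and adjusted p = 0.506 with an estimated correlation). The galactinol and raffinose list rose in 5 of 6 members (5 adjusted over the list alone, adjusted p = 0.0163, and adjusted p = 0.455 with an estimated correlation). GolS2 rose by 2.67 ± 0.46. The list call for ABA receptors ended with median scaling (adjusted p = 0.0539), and those for ABA synthesis (0.0849) and galactinol (0.0577) ended with the authors' table.

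Hormone and defence genes also moved in 300 mM salt. Of 23 jasmonate genes 22 rose (22 adjusted over the list alone), among them CYP94B3, which oxidises the hormone (6.33 ± 0.75), and the storage protein gene VSP1 (4.17 ± 0.30), with adjusted p = 1.05e-09, and adjusted p = 0.4 with an estimated correlation. Of 21 salicylate genes 10 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.0319, and adjusted p = 0.77 with an estimated correlation). BGL2 changed by 2.01 ± 0.34 and PR1 by -1.37 ± 0.35. Senescence genes rose in 11 of 15 cases (13 adjusted over the list alone), led by the sugar transporter gene SAG29 (6.05 ± 0.74), with adjusted p = 3.25e-05, and adjusted p = 0.4 with an estimated correlation. Of 21 phenylpropanoid and flavonoid genes 14 rose and 3 fell (14 and 3 adjusted over the list alone), the anthocyanin genes UF3GT by 2.83 ± 0.34 and LDOX by 2.09 ± 0.29 (adjusted p = 0.00761, and adjusted p = 0.468 with an estimated correlation). The glucosinolate list rose in 11 of 24 members and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0407, and adjusted p = 0.732 with an estimated correlation). MYB76 rose by 1.3 ± 0.15. Of 30 reactive oxygen genes 16 rose and 3 fell (16 and 3 adjusted over the list alone, adjusted p = 0.00645, and adjusted p = 0.508 with an estimated correlation). The zinc finger gene RHL41 rose by 3.95 ± 0.44. With the authors' table the list calls for salicylate (adjusted p = 0.186) and glucosinolate genes (0.0739) ended, the latter also without a filter on dim probes (0.0559).

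Ribosomal protein, cell division and auxin genes fell in 300 mM salt. Of 40 ribosomal protein genes 37 fell and none rose (37 fell and 1 rose adjusted over the list alone), RPL9 by -1.10 ± 0.10 and RPL3B by -1.04 ± 0.10, with adjusted p = 1.35e-10, and adjusted p = 0.487 with an estimated correlation. Of 18 cell division genes 16 fell (18 adjusted over the list alone), such as the cyclin genes CYC1BAT (-1.13 ± 0.15) and CYCB2;1 (-1.03 ± 0.14), with adjusted p = 2.97e-06, and adjusted p = 0.535 with an estimated correlation. Of 24 auxin genes 16 fell and 3 rose (16 and 3 adjusted over the list alone), IAA6 by -1.05 ± 0.16 against a rise of the conjugating enzyme gene GH3.3 by 2.2 ± 0.51 (adjusted p = 0.0129, and adjusted p = 0.59 with an estimated correlation). The photosystem list fell in 7 of 20 members (7 adjusted over the list alone, adjusted p = 0.0432, and adjusted p = 0.788 with an estimated correlation). That call ended with normexp, quantile normalization, median scaling, the strict filter (genes well above background on every array) and the authors' table, where the median turned from -0.18 to 0.23.

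Chaperone genes rose in 300 mM salt without heat. Of 26 heat shock protein genes 18 rose and 4 fell (19 and 4 adjusted over the list alone, adjusted p = 0.000306, and adjusted p = 0.49 with an estimated correlation). AT1G53540, a small heat shock protein gene, rose by 4.05 ± 0.49. Of 20 heat shock factor genes 12 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.00534, and adjusted p = 0.416 with an estimated correlation). HSFA6B rose at least 36.3-fold and HSFA2 by 3.16 ± 0.29. The unfolded protein response list rose in 9 of 16 members (9 adjusted over the list alone, adjusted p = 0.00471, and adjusted p = 0.598 with an estimated correlation). The chaperone gene BIP3 rose by 1.47 ± 0.37. Of the fixed panel genes, the proline synthesis gene P5CS1 rose by 2 ± 0.16 and ERD5, which breaks proline down, fell by 1.15 ± 0.24, although 1 of its 3 other probes pointed up. The sodium exporter gene SOS1 did not pass (0.10 ± 0.09, adjusted p = 0.34), and the sodium transporter gene HKT1 fell by 0.57 ± 0.14, a call that ended with normexp background correction and with the authors' table. HSP101, the peroxidase gene APX2 (at least 2.15-fold) and NRT2.3 also lost their calls with normexp.

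The limma fit of 300 mM salt against control called 13173 of 21860 genes, 6547 up and 6626 down, 3074 of them at least 2-fold (2761 up, 313 down), and 1441 and 256 in a fit of the genes well above background on every array. An exact permutation test on 3 and 3 arrays could not fall below 0.1. The split was 5311 up and 8539 down with median scaling and 12397 up and 802 down with the authors' table (median shift 0.41 log2), and normexp lowered the count to 7577. No camera call was made for ion transport (5 up, 8 down of 24), aquaporins (6 and 6 of 19), proline (4 and 2 of 6), light-harvesting (0 and 1 of 18), Calvin cycle (0 and 5 of 13), chlorophyll synthesis (1 and 6 of 11), dark-induced (3 and 6 of 14), ethylene (6 and 2 of 18), cell wall (5 and 10 of 22), clock (11 and 3 of 20), root marker (2 and 1 of 10), flower and seed marker (1 and 0 of 9) and reference genes (2 and 2 of 11). The median, mean and test of the ion transport, cell wall and root marker lists differed in sign. The control and both salt groups each had a slide of their own, so a slide difference and a treatment difference could not be told apart in any comparison with them.

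**Figure D1:**
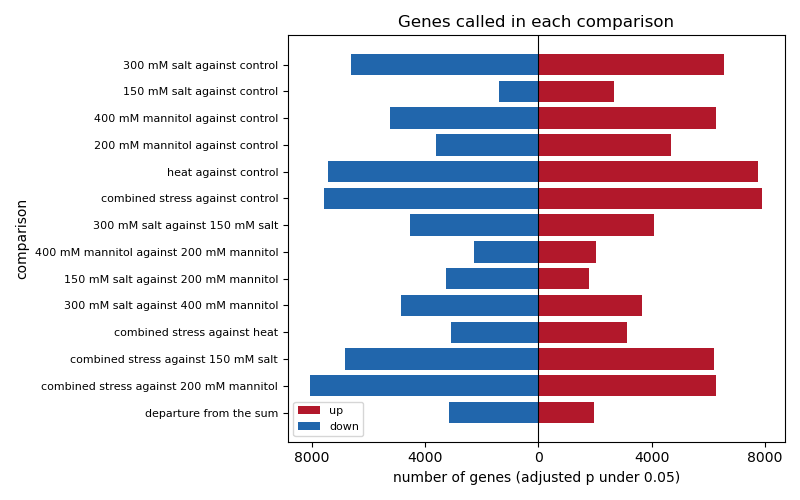
Genes called up (right) and down (left) in each comparison, n = 3 arrays per group. Combined stress against control had the most calls (15473) and 150 mM salt against control the fewest (4042).

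Salt at 150 mM raised dehydration, ABA and jasmonate genes, with fewer calls than 300 mM. LEA7 (7.63 ± 1.03, n = 3 arrays per group), BSMT1 (at least 48.6-fold), UGT76E12 (6.24 ± 0.88), RRTF1 (at least 50.3-fold), the ubiquitin ligase gene PUB19 (6.19 ± 0.41) and LEA4-5 (6.02 ± 0.63) were among the largest rises. The falls of PDF1.2 (-2.21 ± 0.49) and NRT2.3 (-2.04 ± 0.59) lost their calls with normexp, and NRT2.3 also without salt replicate 1 or 3 or control replicate 1 or 3. PYL6 fell by 1.87 ± 0.23. The pectin methylesterase gene PME38 (at least 1.99-fold), the petal gene RBE (at least 1.83-fold) and the defensin-like gene LCR41 (at least 1.78-fold) were called lower on salt arrays that were not above background, and turned direction with normexp background correction.

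Of 20 late embryogenesis abundant and dehydrin genes 18 rose in 150 mM salt (19 adjusted over the list alone), among them LTI65 (3.81 ± 0.61) and LTI78 (2.24 ± 0.20), with adjusted p = 4.58e-17, and adjusted p = 0.142 with an estimated correlation. ABA signalling genes rose in 13 of 16 cases (15 adjusted over the list alone, adjusted p = 8.59e-12, and adjusted p = 0.312 with an estimated correlation). HAI1 rose by 4.43 ± 0.33 and HAI2 by 4.04 ± 0.37. Of 23 jasmonate genes 21 rose and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 5.01e-13, and adjusted p = 0.347 with an estimated correlation). CYP94B3 rose by 5.18 ± 0.75 and VSP1 by 3.28 ± 0.30. Of 9 DREB and CBF genes 7 rose (8 adjusted over the list alone, adjusted p = 4.25e-07, and adjusted p = 0.242 with an estimated correlation). CBF4 rose by 5.85 ± 0.57 and DREB2A by 3.11 ± 0.31. Heat shock protein genes rose in 11 of 26 cases and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.000188, and adjusted p = 0.487 with an estimated correlation), and HSFA2 rose by 2.18 ± 0.29. Ribosomal protein genes fell in 15 of 40 cases and rose in 1 (21 and 1 adjusted over the list alone, adjusted p = 1.12e-07, and adjusted p = 0.542 with an estimated correlation). The cell division list fell in 4 of 18 members (6 adjusted over the list alone, adjusted p = 0.000397, and adjusted p = 0.632 with an estimated correlation). Salicylate genes did not move as a list (0 up, 1 down of 21). NCED3 (1.60 ± 0.32) and P5CS1 (1.05 ± 0.16) rose, and SOS1 (0.06 ± 0.09), HKT1 (-0.05 ± 0.14) and HSP101 (0.27 ± 0.09) did not pass.

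In all 4042 of 21860 genes passed in 150 mM salt, 2659 up and 1383 down, with 1229 and 68 at least 2-fold, and 578 and 34 in a fit of the genes well above background on every array. The split was 1952 and 1852 with quantile normalization, 2261 and 3041 with median scaling, and 2211 and 125 with the authors' table (median shift 0.10 log2). The count was 1533 with normexp, 6759 with array weights and 2669 without salt replicate 3.

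Between the salt doses, the ABA response deepened at 300 mM and the ribosome and division genes went further down. ABA signalling genes rose in 15 of 16 cases (15 adjusted over the list alone), AFP1 by 1.59 ± 0.30 (n = 3 arrays per group), with adjusted p = 1.92e-09, and adjusted p = 0.347 with an estimated correlation. Late embryogenesis abundant and dehydrin genes rose in 15 of 20 cases (15 adjusted over the list alone, adjusted p = 1.27e-09, and adjusted p = 0.347 with an estimated correlation). Ribosomal protein genes fell in 31 of 40 cases (34 adjusted over the list alone, adjusted p = 1.22e-09, and adjusted p = 0.506 with an estimated correlation). RPL9 changed by -0.76 ± 0.10. Cell division genes fell in 14 of 18 (15 adjusted over the list alone, adjusted p = 7.02e-06, and adjusted p = 0.537 with an estimated correlation). CYC1BAT changed by -0.83 ± 0.15. Salicylate genes rose in 12 of 21 cases (13 adjusted over the list alone, adjusted p = 0.000164, and adjusted p = 0.631 with an estimated correlation). The rises of the transporter gene ABCA6 (at least 4.81-fold) and of PME38 (at least 6.75-fold) lost their calls with normexp, as did the fall of CRK30 (-2.31 ± 0.37, 1 of 3 arrays at 300 mM), while PYL6 fell by 2.33 ± 0.23. Of 21860 genes 4067 rose and 4550 fell, with 975 and 140 at least 2-fold, and 389 and 72 in a fit of the genes well above background on every array. The split was 1640 and 2407 with normexp (median shift -0.13 log2) and 8406 and 284 with the authors' table (0.31 log2). Auxin genes fell in 9 of 24 cases (9 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.59 with an estimated correlation), a call that ended with normexp and a median (-0.22) that turned to 0.09 with the authors' table.

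Mannitol at 400 mM raised dehydration, defence and glucosinolate genes and lowered auxin, cell wall and sugar-starvation genes. Among the largest rises were those of LTP4 (7.92 ± 0.57, n = 3 arrays per group), BSMT1 (at least 49-fold), LTP3 (6.32 ± 0.43), LEA7 (6.10 ± 1.03), SAG29 (5.70 ± 0.74) and the small heat shock protein gene ATHSP22.0 (at least 10.8-fold). PYL6 (-3.29 ± 0.23), CRK30 (-2.88 ± 0.37), MEE3 (-2.85 ± 0.22) and the ethylene synthesis gene ACS4 (-2.40 ± 0.26) were among the largest falls. DIR5, a dirigent protein gene (at least 1.92-fold), and the seed gene M17 (at least 1.64-fold) were called lower on mannitol arrays that were not above background. The direction of DIR5 and M17 turned with normexp, which also ended the calls of CRK30 and ACS4, and the call of DIR5 ended without control replicate 2 or mannitol replicate 1 or 2.

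Salicylate genes rose in 18 of 21 cases in 400 mM mannitol (19 adjusted over the list alone), among them PR5 (3.16 ± 0.29), BGL2 (2.63 ± 0.34), ALD1 (2.36 ± 0.46) and FMO1 (2.22 ± 0.41), which act in pathogen defence (adjusted p = 1.09e-05, and adjusted p = 0.561 with an estimated correlation). Of 20 late embryogenesis abundant and dehydrin genes 19 rose (19 adjusted over the list alone, adjusted p = 8.44e-09, and adjusted p = 0.347 with an estimated correlation). LTI65 rose by 3.74 ± 0.61 and LTI78 by 2.55 ± 0.20, and of 16 ABA signalling genes 14 (14 adjusted over the list alone, adjusted p = 2.44e-07, and adjusted p = 0.4 with an estimated correlation). HAI2 rose by 4.24 ± 0.37 and HAI1 by 3.97 ± 0.33. Jasmonate genes rose in 19 of 23 cases (20 adjusted over the list alone, adjusted p = 6.05e-06, and adjusted p = 0.506 with an estimated correlation). TAT3 rose by 4.79 ± 0.50. Ethylene genes rose in 8 of 18 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0407, and adjusted p = 0.638 with an estimated correlation). ERF1 rose by 3.26 ± 0.23. Glucosinolate genes rose in 19 of 24 cases (19 adjusted over the list alone, adjusted p = 2.13e-05, and adjusted p = 0.508 with an estimated correlation). CYP79F1 rose by 1.23 ± 0.19. Heat shock protein genes rose in 17 of 26 cases (17 adjusted over the list alone, adjusted p = 0.00013, and adjusted p = 0.486 with an estimated correlation). HSP21 rose at least 8.12-fold. The list call for ethylene genes ended with the authors' table (adjusted p = 0.0901).

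Auxin genes fell in 14 of 24 cases in 400 mM mannitol (14 fell and 1 rose adjusted over the list alone, adjusted p = 0.000237, and adjusted p = 0.471 with an estimated correlation). IAA29 changed by -2.07 ± 0.20. Cell wall expansion genes fell in 14 of 22 cases and rose in 3 (14 and 3 adjusted over the list alone, adjusted p = 0.00285, and adjusted p = 0.4 with an estimated correlation). The expansin gene EXPA8 changed by -1.99 ± 0.22 and XTH4 by -1.61 ± 0.15. Dark- and sugar-starvation-induced genes fell in 8 of 14 cases (8 adjusted over the list alone, adjusted p = 9.25e-05, and adjusted p = 0.344 with an estimated correlation). DIN10 changed by -1.82 ± 0.14. Chlorophyll synthesis genes fell in 9 of 11 (9 adjusted over the list alone, adjusted p = 0.000158, and adjusted p = 0.487 with an estimated correlation). HEMA1 changed by -0.77 ± 0.06. P5CS1 (1.31 ± 0.16) and NCED3 (1.39 ± 0.32) rose, and HSP101, SOS1 (0.20 ± 0.09) and HKT1 (0.13 ± 0.14) did not pass. Of 21860 genes 6287 rose and 5232 fell, with 2702 and 238 at least 2-fold, and 1419 and 211 in a fit of the genes well above background on every array. The split was 4607 and 3740 with normexp (median shift 0.14 log2), 4837 and 6662 with quantile normalization, 4785 and 8292 with median scaling (-0.13) and 7918 and 971 with the authors' table (0.23).

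Mannitol at 200 mM also raised defence genes and gave few strong falls. BSMT1 (at least 35.2-fold), LTP4 (6.39 ± 0.57, n = 3 arrays per group), the defensin-like gene LCR67 (at least 8.06-fold), LTP3 (4.80 ± 0.43), the terpene synthase gene TPS04 (4.45 ± 0.74) and SAG29 (4.41 ± 0.74) were among the largest rises. The phosphatase gene PAP14 (-2.72 ± 0.48), MEE3 (-1.67 ± 0.22), CRK30 (-1.62 ± 0.37) and PYL6 (-1.49 ± 0.23) were among the largest falls, and DIR5 (at least 1.74-fold) was called lower on mannitol arrays that were not above background. Normexp ended the calls of LCR67, DIR5 and CRK30, and that of DIR5 ended without mannitol replicate 1. Of 21 salicylate genes 15 rose (18 adjusted over the list alone, adjusted p = 3.53e-05, and adjusted p = 0.593 with an estimated correlation). PR5 rose by 2.52 ± 0.29, BGL2 by 2.07 ± 0.34 and ALD1 by 1.97 ± 0.46. Of 15 senescence genes 14 rose (14 adjusted over the list alone, adjusted p = 1.02e-05, and adjusted p = 0.4 with an estimated correlation), and of 23 jasmonate genes 18 (19 adjusted over the list alone, adjusted p = 1.85e-05, and adjusted p = 0.51 with an estimated correlation). TAT3 rose by 3.82 ± 0.50.

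ABA signalling genes rose in 14 of 16 cases in 200 mM mannitol (14 adjusted over the list alone, adjusted p = 4.26e-06, and adjusted p = 0.455 with an estimated correlation). HAI1 rose by 3.41 ± 0.33 and HAI2 by 2.23 ± 0.37. Late embryogenesis abundant and dehydrin genes rose in 17 of 20 (19 adjusted over the list alone, adjusted p = 7.1e-07, and adjusted p = 0.4 with an estimated correlation). LEA7 rose by 4.15 ± 1.03 and LTI78 by 1.15 ± 0.20. Ribosomal protein genes fell in 29 of 40 cases and rose in 1 (34 and 1 adjusted over the list alone, adjusted p = 2.82e-09, and adjusted p = 0.508 with an estimated correlation). HSP101 fell by 0.32 ± 0.09, a call that ended with normexp, with the authors' table, and without control replicate 2 or mannitol replicate 3, while ERD5 (-0.34 ± 0.24), HSFA2 (0.33 ± 0.29), SOS1 and HKT1 did not pass. Of 21860 genes 4697 rose and 3603 fell. Of these, 2122 and 29 changed at least 2-fold, and 954 and 11 did so in a fit of the genes well above background on every array. The split was 3728 and 5309 with quantile normalization, 3605 and 6967 with median scaling (median shift -0.11 log2) and 7170 and 96 with the authors' table (0.25). The count fell to 3194 with normexp and to 5419 without mannitol replicate 1.

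The higher mannitol dose raised flavonoid and chaperone genes and lowered starvation-induced and auxin genes below the lower dose. Phenylpropanoid and flavonoid genes rose in 13 of 21 cases and fell in 1 (14 and 1 adjusted over the list alone, n = 3 arrays per group, adjusted p = 2.44e-07, and adjusted p = 0.142 with an estimated correlation). UF3GT rose by 1.98 ± 0.34 and DFR by 1.89 ± 0.31. Dark- and sugar-starvation-induced genes fell in 9 of 14 cases (10 adjusted over the list alone, adjusted p = 1.87e-10, and adjusted p = 0.114 with an estimated correlation). AT4G35770 changed by -2.01 ± 0.30 and DIN10 by -1.59 ± 0.14. Auxin genes fell in 13 of 24 cases (14 adjusted over the list alone, adjusted p = 1.07e-06, and adjusted p = 0.363 with an estimated correlation). IAA29 changed by -1.71 ± 0.20. Heat shock protein genes rose in 13 of 26 cases (14 adjusted over the list alone), ATHSP22.0 at least 8.97-fold and HSP21 by 3.69 ± 0.64 (1 of 3 arrays at 200 mM), calls that ended with normexp (adjusted p = 4.77e-08 for the list, and adjusted p = 0.347 with an estimated correlation). The iron-deficiency factor gene BHLH100 rose by 3.41 ± 0.70, and PYL6 fell by 1.80 ± 0.23 and BXL1, a xylosidase gene, by 1.73 ± 0.09, the calls of PYL6 and IAA29 ending with normexp. Of 21860 genes 2030 rose and 2261 fell. Of these, 204 and 124 changed at least 2-fold, and 133 and 89 did so in a fit of the genes well above background on every array. With slide as a fixed block 920 genes passed (403 up, 517 down), and inside the slide that held both doses (3 arrays against 1) 1 gene passed. For this pair the block rests on that slide alone, so both give the same fold changes. The list medians were 0.75 against 0.81 for flavonoid genes, -0.76 against -0.78 for starvation genes, -0.44 against -0.43 for auxin and 0.41 against 0.51 for heat shock proteins, with the slide block against the unblocked fit. The count was 1039 with the authors' table, 8689 with array weights, 2727 from these 6 arrays alone and 2441 without 400 mM replicate 3, and the split was 1355 and 1574 with normexp (median shift 0.13 log2).

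Salt at 150 mM and mannitol at 200 mM differed in salicylate genes, which were lower in salt in 17 of 21 cases (18 adjusted over the list alone, n = 3 arrays per group, adjusted p = 1.84e-08, and adjusted p = 0.487 with an estimated correlation). PR5 differed by -3.13 ± 0.29 and ALD1 by -2.31 ± 0.46. PDF1.2 (-5.24 ± 0.49), the methyltransferase gene PXMT1 (-3.92 ± 0.49) and LCR67 (at least 6.29-fold) were among the lowest, and CBF4 (5.11 ± 0.57), HSFA6B (4.91 ± 0.84, 1 of 3 mannitol arrays), RRTF1 (4.44 ± 0.71) and the ethylene response factor gene RAP2.6 (3.76 ± 0.61) among the highest. Normexp ended the calls of LCR67, HSFA6B and ALD1. Phenylpropanoid and flavonoid genes were higher in salt in 15 of 21 cases and lower in 1 (15 and 1 adjusted over the list alone, adjusted p = 1.33e-06, and adjusted p = 0.203 with an estimated correlation). UF3GT differed by 1.76 ± 0.34. DREB and CBF genes were higher in salt in 5 of 9 (5 adjusted over the list alone, adjusted p = 0.00209, and adjusted p = 0.455 with an estimated correlation). Of 21860 genes 1784 were higher and 3257 lower in salt. Of these, 201 and 1212 changed at least 2-fold, and 135 and 458 did so in a fit of the genes well above background on every array. The split was 2504 and 2486 with quantile normalization, 2370 and 2795 with median scaling, and 280 and 3033 with the authors' table (median shift -0.15 log2), and the count was 1278 with normexp and 3262 without mannitol replicate 1. The list call for DREB and CBF genes ended with the strict filter (adjusted p = 0.0514). As the doses in mM differed (150 and 200), solute and strength of dose could not be told apart.

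At the higher doses salt stood above mannitol in DREB and ABA genes and below it in salicylate and cell division genes. The doses in mM differed here too (300 and 400), so solute and strength of dose could not be told apart. DREB and CBF genes were higher in 7 of 9 cases (7 adjusted over the list alone, n = 3 arrays per group, adjusted p = 6.58e-05, and adjusted p = 0.363 with an estimated correlation). CBF4 differed by 5.05 ± 0.57 and DREB2A by 2.57 ± 0.31. ABA signalling genes were higher in 10 of 16 cases (12 adjusted over the list alone, adjusted p = 1.65e-05, and adjusted p = 0.486 with an estimated correlation), and dark- and sugar-starvation-induced genes in 10 of 14 (10 adjusted over the list alone, adjusted p = 1.04e-05, and adjusted p = 0.242 with an estimated correlation). Cell division genes were lower in 17 of 18 cases (18 adjusted over the list alone, adjusted p = 2.61e-07, and adjusted p = 0.506 with an estimated correlation). CYC1BAT differed by -0.99 ± 0.15. Salicylate genes were lower in 10 of 21 (13 lower and 1 higher adjusted over the list alone, adjusted p = 0.00245, and adjusted p = 0.698 with an estimated correlation). PR5 differed by -3.42 ± 0.29 and PR1 by -1.88 ± 0.35. ABR1 (5.24 ± 0.61), an ABA-responsive repressor gene, and the nitrate transporter gene NRT1.8 (4.80 ± 0.75) were among the highest, and PDF1.2 (-6.34 ± 0.49), PXMT1 (-4.45 ± 0.49), the camalexin gene CYP71A13 (-4.40 ± 0.52) and the lipase gene GLIP1 (-3.97 ± 0.40) among the lowest. Of 21860 genes 3677 were higher and 4865 lower in salt. Of these, 585 and 931 changed at least 2-fold, and 383 and 493 did so in a fit of the genes well above background on every array. The split was 2270 and 3437 with normexp (median shift -0.14 log2) and 4149 and 1446 with the authors' table (0.18), a lower count of 5595.

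**Figure D2:**
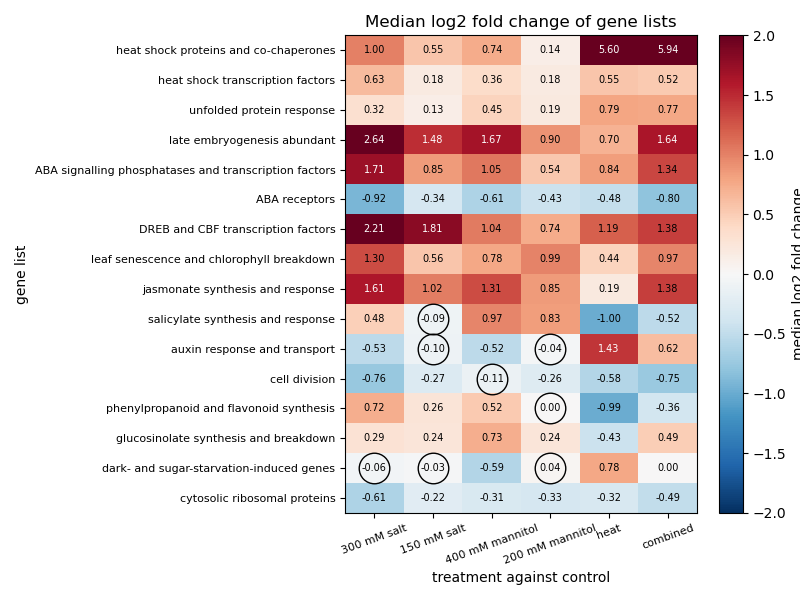
Median log2 fold change of gene lists (vertical) in each treatment against control (horizontal), n = 3 arrays per group. A circle marks a median whose sign turned under another scaling or background correction, and salicylate genes stood at 0.97 in 400 mM mannitol and at -1 in heat.

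Heat of 35 °C for 4 h raised chaperone, aquaporin and auxin genes and lowered flavonoid, salicylate and cell division genes. The small heat shock protein genes HSP23.6-MITO (at least 1110-fold), HSP17.6A (at least 251-fold), ATHSP22.0 (at least 126-fold), HSP21 (at least 84.3-fold) and HSP17.6II (at least 225-fold) and the chaperone gene HSP70 (7.31 ± 0.26, n = 3 arrays per group) were among the largest rises. TBL15, an acetyltransferase gene (-4.93 ± 0.30, 1 of 3 heat arrays), the defence gene PCC1 (-4.42 ± 0.23), GSTF12, which carries anthocyanins to the vacuole (-4.24 ± 0.27), the anthocyanin genes DFR (-4.23 ± 0.31) and LDOX (-4.22 ± 0.29), and AT5MAT (-3.97 ± 0.24) were among the largest falls, although another probe of GSTF12 gave only -0.40.

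In heat 25 of 26 heat shock protein genes rose and 1 fell (25 and 1 adjusted over the list alone), with adjusted p = 1.54e-14, and adjusted p = 0.142 with an estimated correlation, and HSP101, which dissolves aggregates, rose by 4.28 ± 0.09. Heat shock factor genes rose in 11 of 20 cases (11 adjusted over the list alone, adjusted p = 0.00388, and adjusted p = 0.4 with an estimated correlation). HSFA2 rose by 6.07 ± 0.29. Unfolded protein response genes rose in 12 of 16 cases and fell in 1 (12 and 1 adjusted over the list alone), ATERDJ3A by 3.62 ± 0.18 and BIP2 by 1.85 ± 0.11 against a fall of BIP3 by -1.80 ± 0.37 (adjusted p = 0.000189, and adjusted p = 0.508 with an estimated correlation). Aquaporin genes rose in 17 of 19 cases (17 adjusted over the list alone, adjusted p = 4.49e-05, and adjusted p = 0.4 with an estimated correlation). RD28 rose by 3.35 ± 0.11 and PIP2B by 1.54 ± 0.07. Auxin genes rose in 20 of 24 cases and fell in 3 (20 and 3 adjusted over the list alone), IAA29 by 2.77 ± 0.20 and the synthesis genes YUC9 by 2.66 ± 0.25 and YUC8 by 2.59 ± 0.19 (adjusted p = 3.87e-05, and adjusted p = 0.402 with an estimated correlation). Dark- and sugar-starvation-induced genes rose in 11 of 14 cases (11 adjusted over the list alone, adjusted p = 0.000302, and adjusted p = 0.347 with an estimated correlation). AT4G35770 rose by 2.75 ± 0.30 and the asparagine synthetase gene ASN1 by 1.37 ± 0.20.

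Phenylpropanoid and flavonoid genes fell in 19 of 21 cases in heat and rose in 1 (19 and 1 adjusted over the list alone, adjusted p = 1.63e-05, and adjusted p = 0.268 with an estimated correlation). UF3GT changed by -3.64 ± 0.34. Salicylate genes fell in 16 of 21 cases (16 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.698 with an estimated correlation). WRKY54 changed by -2.40 ± 0.16 and PR5 by -2.33 ± 0.29. Cell division genes fell in 14 of 18 cases (14 adjusted over the list alone), the replication genes PCNA1 by -1.73 ± 0.10 and MCM2 by -1.39 ± 0.08 (adjusted p = 0.00106, and adjusted p = 0.667 with an estimated correlation). Glucosinolate genes fell in 14 of 24 cases and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 0.0186, and adjusted p = 0.698 with an estimated correlation). CYP79F1 changed by -1.15 ± 0.19 and MYB28 by -1.11 ± 0.09. Ribosomal protein genes fell in 26 of 40 and rose in 2 (26 and 2 adjusted over the list alone, adjusted p = 0.00109, and adjusted p = 0.698 with an estimated correlation). ABA signalling genes rose in 12 of 16 cases (12 adjusted over the list alone, adjusted p = 0.000634, and adjusted p = 0.537 with an estimated correlation). HAI1 rose by 3.5 ± 0.33, while the late embryogenesis abundant and dehydrin list gave no camera call (13 up, 3 down of 20), COR15B falling by 2.02 ± 0.12. The glucosinolate call ended with quantile normalization (adjusted p = 0.0534).

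Further single genes moved in heat: DREB2A (3.67 ± 0.31), GolS2 (4.35 ± 0.46), the ethylene synthesis gene ACS8 (4.34 ± 0.26), APX2 (at least 26.2-fold) and HKT1 (0.86 ± 0.14) rose, and PYL6 (-2.98 ± 0.23), ERD5 (-1.76 ± 0.24) and the clock gene LHY (-2.81 ± 0.17) fell. LTI78 (-0.07 ± 0.20) and LTI65 (1.38 ± 0.61) did not pass, and the call of HKT1 ended with normexp. Of 21860 genes 7764 rose and 7433 fell. Of these, 2665 and 1371 changed at least 2-fold, and 1513 and 1186 did so in a fit of the genes well above background on every array. The split was 6076 and 9253 with reference gene scaling (median shift -0.13 log2) and 8068 and 4198 with the authors' table (0.14), and normexp lowered the count to 10007.

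Combined stress (150 mM salt, 200 mM mannitol and heat) joined the heat shock genes with the dehydration and jasmonate genes. HSP23.6-MITO (at least 2030-fold), ATHSP22.0 (at least 452-fold), HSP21 (at least 428-fold), HSP17.6A (at least 354-fold), LTP4 (9.79 ± 0.57, n = 3 arrays per group) and HSP17.6II (at least 369-fold) were among the largest rises. PYL6 (-5.45 ± 0.23), CRK30 (-4.10 ± 0.37, 1 of 3 stress arrays) and MEE3 (-3.87 ± 0.22) were among the largest falls. The nitrate transporter genes NRT2.5 (at least 3.89-fold) and NRT2.3 (at least 8.07-fold) and the cell wall gene XTH20 (at least 6.2-fold) were called lower on stress arrays that were not above background, and these calls ended with normexp.

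Of 26 heat shock protein genes 25 rose in combined stress (25 adjusted over the list alone, adjusted p = 3.11e-16, and adjusted p = 0.142 with an estimated correlation), HSP101 by 4.47 ± 0.09, and of 20 heat shock factor genes 13 (13 adjusted over the list alone, adjusted p = 0.000425, and adjusted p = 0.347 with an estimated correlation). HSFA2 rose by 6.62 ± 0.29. Jasmonate genes rose in 22 of 23 cases and fell in 1 (22 and 1 adjusted over the list alone, adjusted p = 4.76e-05, and adjusted p = 0.537 with an estimated correlation). VSP1 rose by 3.88 ± 0.30 and VSP2 by 3.68 ± 0.27. ABA signalling genes rose in 15 of 16 cases (15 adjusted over the list alone, adjusted p = 1.45e-06, and adjusted p = 0.416 with an estimated correlation). HAI1 rose by 5.71 ± 0.33. Late embryogenesis abundant and dehydrin genes rose in 18 of 20 (18 adjusted over the list alone, adjusted p = 2.35e-06, and adjusted p = 0.402 with an estimated correlation). LEA7 rose by 7.80 ± 1.03 and LTI78 by 1.26 ± 0.20. Aquaporin genes rose in 12 of 19 cases and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.0059, and adjusted p = 0.537 with an estimated correlation). RD28 rose by 3.25 ± 0.11. Cell division genes fell in 15 of 18 cases (16 adjusted over the list alone, adjusted p = 0.00018, and adjusted p = 0.623 with an estimated correlation). CYCB1;1 changed by -1.56 ± 0.13. Ribosomal protein genes fell in 31 of 40 with 4 rises (31 and 5 adjusted over the list alone, adjusted p = 7.91e-05, and adjusted p = 0.667 with an estimated correlation). AT4G31700 changed by -1.27 ± 0.14.

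Salicylate genes were split in combined stress: 2 rose and 10 fell of 21, BGL2 by 2.04 ± 0.34 and PR5 by 1.67 ± 0.29 against PR1 by -2.05 ± 0.35 and WRKY54 by -1.92 ± 0.16, without a camera call. Flavonoid genes were split too, 3 up and 11 down of 21, with the anthocyanin regulator gene AT1G56650 up by 2.72 ± 0.19 and FLS1 down by -2.06 ± 0.12. DREB2A (4.26 ± 0.31), GolS2 (4.90 ± 0.46), APX2 (at least 70.2-fold), NCED3 (1.92 ± 0.32), P5CS1 (1.23 ± 0.16) and SOS1 (0.47 ± 0.09) rose, ERD5 fell by 2.04 ± 0.24, and HKT1 (0.08 ± 0.14) did not pass. Of 21860 genes 7912 rose and 7561 fell. Of these, 2777 and 1407 changed at least 2-fold, and 1700 and 1199 did so in a fit of the genes well above background on every array.

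Against heat alone, combined stress was higher in dehydration, jasmonate, flavonoid and glucosinolate genes and lower in auxin, starvation-induced and aquaporin genes. Late embryogenesis abundant and dehydrin genes were higher in 17 of 20 cases (18 adjusted over the list alone, n = 3 arrays per group, adjusted p = 3.26e-12, and adjusted p = 0.242 with an estimated correlation). COR15A differed by 3.64 ± 0.22. Phenylpropanoid and flavonoid genes were higher in 16 of 21 and lower in 1 (16 and 1 adjusted over the list alone, adjusted p = 3.03e-09, and adjusted p = 0.123 with an estimated correlation). UF3GT differed by 3.79 ± 0.34. Glucosinolate genes were higher in 17 of 24 and lower in 1 (17 and 2 adjusted over the list alone, adjusted p = 6.73e-09, and adjusted p = 0.4 with an estimated correlation). CYP79F1 differed by 1.92 ± 0.19. Jasmonate genes were higher in 18 of 23 (20 adjusted over the list alone, adjusted p = 1.87e-10, and adjusted p = 0.4 with an estimated correlation). VSP1 differed by 3.54 ± 0.30. Auxin genes were lower in 15 of 24 cases and higher in 1 (18 and 1 adjusted over the list alone, adjusted p = 2.74e-08, and adjusted p = 0.334 with an estimated correlation). YUC8 differed by -1.99 ± 0.19. Aquaporin genes were lower in 10 of 19 (12 adjusted over the list alone, adjusted p = 0.00126, and adjusted p = 0.487 with an estimated correlation). Starvation-induced genes were lower in 9 of 14 cases (10 adjusted over the list alone, adjusted p = 2.88e-07, and adjusted p = 0.142 with an estimated correlation). AT3G15450 differed by -1.60 ± 0.12. BSMT1 (at least 43.4-fold), SAG29 (5.75 ± 0.74) and NATA1, an acetyltransferase gene (5.52 ± 0.57), were among the highest, and M17 was lower (at least 6.17-fold, a call that ended with normexp). HSP101 did not differ (0.19 ± 0.09, adjusted p = 0.14), while the heat shock protein list had a median of 0.37 above heat (0.4 with the slide block).

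Of 21860 genes 3118 were higher and 3103 lower in combined stress than in heat. Of these, 645 and 341 changed at least 2-fold, and 524 and 217 did so in a fit of the genes well above background on every array. Slide as a fixed block left 2991 genes (1639 up, 1352 down), and the slide with both groups (3 arrays against 1) none. Here too both rest on the shared slide. They gave list medians of 1.62 for dehydration genes (1.48 unblocked), 0.70 for flavonoid (0.68), 0.62 for glucosinolate (0.69), 0.97 for jasmonate (1.06), -0.82 for auxin (-0.79), -0.32 for aquaporin (-0.28) and -0.69 for starvation-induced genes (-0.68). The split was 3621 and 2231 with reference gene scaling and 1042 and 2608 with the authors' table (median shift -0.14 log2), and the count was 3040 with normexp, 10744 with array weights and 2831 from these 6 arrays alone.

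Against 150 mM salt alone, combined stress raised heat shock genes, with HSP21 at least 334-fold, ATHSP22.0 at least 352-fold and HSP23.6-MITO by 9.74 ± 0.63 (n = 3 arrays per group). Of 26 heat shock protein genes 25 were higher (25 adjusted over the list alone, adjusted p = 6.19e-20, and adjusted p = 0.114 with an estimated correlation), and aquaporin genes were higher in 12 of 19 cases and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.000698, and adjusted p = 0.487 with an estimated correlation). RD28 differed by 2.99 ± 0.11. Flavonoid genes were lower in 14 of 21 cases and higher in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.00198, and adjusted p = 0.4 with an estimated correlation). UF3GT differed by -1.86 ± 0.34, and CBF4 was lower by -2.52 ± 0.57. PYL6 (-3.58 ± 0.23) was among the lowest. Of 21860 genes 6198 were higher and 6848 lower. Of these, 1073 and 1030 changed at least 2-fold, and 780 and 822 did so in a fit of the genes well above background on every array. The split was 3909 and 5201 with normexp (median shift -0.17 log2), 4871 and 8159 with reference gene scaling and 3494 and 6392 with the authors' table (-0.10).

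Against 200 mM mannitol alone, 25 of 26 heat shock protein genes were higher in combined stress (25 adjusted over the list alone, adjusted p = 6.19e-20, and adjusted p = 0.114 with an estimated correlation), HSP23.6-MITO by 11.76 ± 0.63 (1 of 3 mannitol arrays, n = 3 arrays per group), ATHSP22.0 at least 375-fold and HSP101 by 4.79 ± 0.09. Salicylate genes were lower in 18 of 21 cases (18 adjusted over the list alone, adjusted p = 0.000131, and adjusted p = 0.631 with an estimated correlation). FMO1 differed by -2.27 ± 0.41. The glucanase gene BG3 (-4.48 ± 0.31, another probe -0.67) was among the lowest, and NRT2.5 was lower at least 5.73-fold, a call that ended with normexp. Jasmonate genes were higher in 11 of 23 cases and lower in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.0126, and adjusted p = 0.698 with an estimated correlation), with a median of 0.58 that turned to -0.31 with the slide block. Of 21860 genes 6280 were higher and 8049 lower. Of these, 1065 and 1860 changed at least 2-fold, and 904 and 1180 did so in a fit of the genes well above background on every array. Slide as a fixed block left 4266 genes (2031 up, 2235 down), and 91.5% of the 14329 genes called without it kept direction. List medians were 5.37 for heat shock proteins (5.53 unblocked) and -1.43 for salicylate (-1.28). Other lists moved more, such as DREB and CBF genes (0.05 to 0.78), galactinol (0.49 to 1.22), flavonoid genes (-0.2 to -0.55) and root markers (-0.66 to 0.11). The split was 4831 and 9647 with reference gene scaling (median shift -0.11 log2) and 2577 and 10251 with the authors' table (-0.25), and normexp lowered the count to 9531.

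Compared with the sum of the responses to 150 mM salt, 200 mM mannitol and heat, the combined response was smaller for ABA and DREB genes. DREB and CBF genes lay below the sum in 7 of 9 cases (8 adjusted over the list alone, n = 3 arrays per group, adjusted p = 0.000302, and adjusted p = 0.4 with an estimated correlation). DREB2A differed by -3.41 ± 0.61 and CBF4, well above background on 2 of 3 control arrays, by -4.43 ± 1.13. ABA signalling genes lay below it in 10 of 16 cases (11 adjusted over the list alone, adjusted p = 0.00015, and adjusted p = 0.508 with an estimated correlation). HAI1 differed by -5.64 ± 0.67. Late embryogenesis abundant and dehydrin genes lay below it in 10 of 20 with 1 above (10 and 1 adjusted over the list alone, adjusted p = 0.00133, and adjusted p = 0.543 with an estimated correlation). LEA7 differed by -6.91 ± 2.06 and LTI78 by -2.06 ± 0.41. Starvation-induced genes lay below it in 8 of 14 cases (8 adjusted over the list alone, adjusted p = 0.000251, and adjusted p = 0.347 with an estimated correlation). AT4G35770 differed by -3.40 ± 0.60. Ribosomal protein genes lay above it in 14 of 40 cases and below in 1 (16 and 1 adjusted over the list alone, adjusted p = 3.44e-07, and adjusted p = 0.546 with an estimated correlation), with a median of 0.48 that turned to -0.02 with the authors' table, and flavonoid genes in 7 of 21 (10 adjusted over the list alone, adjusted p = 0.000227, and adjusted p = 0.347 with an estimated correlation). Among genes well above background on every control array, large departures were those of the iron-deficiency factor genes BHLH100 (5.04 ± 1.41), bHLH39 (3.82 ± 0.85) and bHLH38 (3.63 ± 0.86) and of LTP4 (-7.86 ± 1.13). The 3 iron-deficiency genes were not well above background on all heat arrays.

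The calls of BHLH100, bHLH39, bHLH38, CBF4 and LEA7 as departures ended with normexp, that of CBF4 also with quantile normalization, and those of BHLH100 and LEA7 without control replicate 1 or 2. HSP101 did not depart from the sum (0.24 ± 0.19). Of 21860 genes 1950 lay above the sum and 3158 below. Of these, 185 and 2185 changed at least 2-fold, and 165 and 1144 did so in a fit of the genes well above background on every array. The split was 556 and 713 with normexp (median shift -0.12 log2), 3082 and 2336 with quantile normalization, 3862 and 2539 with median scaling (0.15) and 46 and 5634 with the authors' table (-0.50), and array weights raised the count to 7879. With the authors' table the list call for late embryogenesis abundant and dehydrin genes as departures ended (adjusted p = 0.0631).

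**Figure D3:**
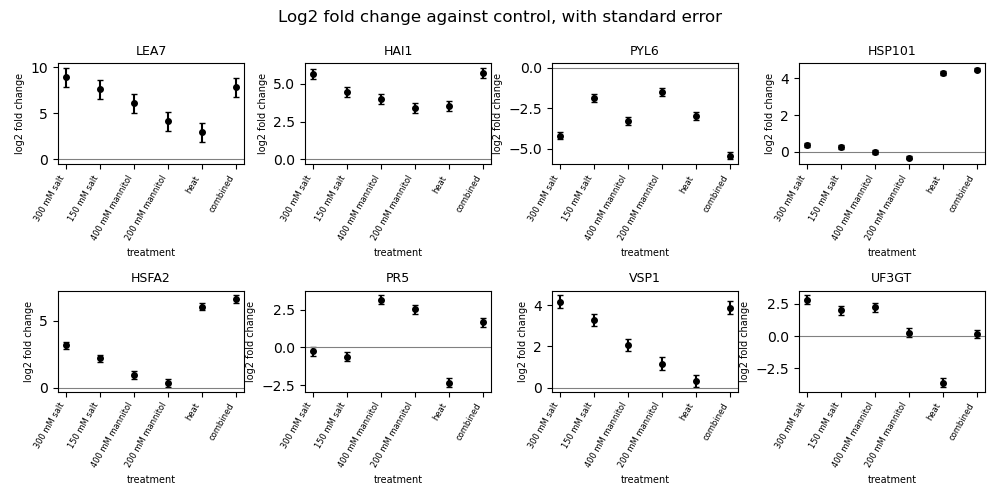
Log2 fold change with standard error of 8 genes (panels) in each treatment against control (horizontal), n = 3 arrays per group. HSP101 stood at 4.28 in heat and 4.47 in combined stress, and PYL6 was lowest in combined stress (-5.45).

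LTP4, LTP3, HAI1, PUB19 and LEA7 rose in all 6 treatments, with smallest rises of 5.34, 3.42, 3.41, 3.02 and 2.94 log2, and CRK30, PYL6, PYL4 and MEE3 fell in all 6, with smallest falls of -1.62, -1.49, -0.94 and -0.92 (n = 3 arrays per group). In all 1353 genes were up in all 6 treatments and 483 down, where independent lists would give 6.33 and 1.94. Simulated unchanged groups that shared simulated controls gave at most 0, and the real control arrays did not enter. These series held no changed gene, so few calls could pass, and they do not show what the shared controls add to the real calls. At least 2-fold, 684 were up and 5 down. The count was 227 in a fit of the genes well above background on every array, and 570 of the 684 rises were among the dimmest 20% of genes. The 4 osmotic treatments shared 1663 rises and 660 falls (49.2 and 16.5 expected). Normexp lowered the shared count from 1836 to 491, ending the calls of CRK30 and MEE3 in 150 mM salt and of CRK30 in both mannitol groups. The rise of LEA7 in heat ended with normexp and without control replicate 1 or 2 or heat replicate 2 or 3. Fold changes of heat and combined stress correlated at 0.85 and those of 400 and 200 mM mannitol at 0.902, where simulated unchanged groups gave 0.498 and 0.5, with covariances of 0.738 and 0.531 against 0.0181 and 0.0183. The lowest correlation, 0.533 between 300 mM salt and heat, stood against 0.498 simulated, with a covariance of 0.421 against 0.0181. Unchanged groups of equal size that share controls correlate near 0.5 by construction. The simulated correlations therefore set no baseline where many genes changed. The simulation also held no slide difference. Neither the correlations nor the covariances could separate a shared response from control arrays that read differently. Since 3 control arrays are too few to give each treatment controls of its own, part of the excess of shared calls over independent lists may come from the shared controls.

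**Figure D4:**
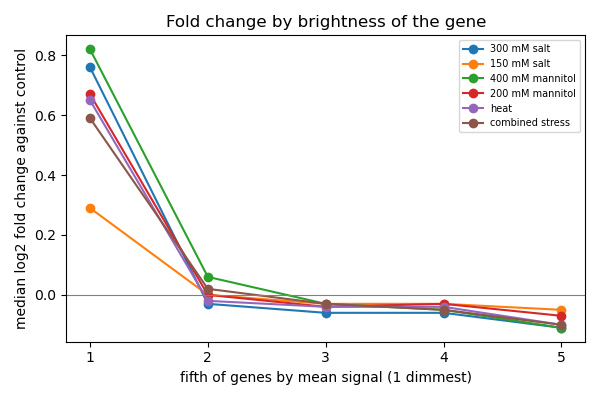
Median log2 fold change against control (vertical) in 5 equal parts of the genes ordered by mean signal (horizontal, 1 the dimmest), n = 3 arrays per group. The dimmest part stood at 0.76 in 300 mM salt and 0.82 in 400 mM mannitol, the brightest at -0.11 in both.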

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

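The tests of the dim-gene pattern and of brightness and scaling for the departures were chosen after the values they measure were seen, and those of the salicylate genes and of falls after rises in several stresses after the patterns were seen but before those values. The spike-in probe that was dimmest over all arrays, with 32 spots and an RNA added in a fixed amount, was at least 0.34 log2 higher in every treatment group than in control after scaling, and the second dimmest over all arrays at least 1.16 higher (control 1.28 ± 0.08, mean ± standard deviation of 3 arrays, below the other probe's 2.09 there). The other 8 of 10 spike-in probes did not rise in every treatment. Among 6440 tested probes without a locus here, 583 were at least 2-fold above control in all 6 treatments. Both are signals in probes that the gene tests left out.

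Rises of at least 2-fold against control lay mostly among dim genes: of 684 genes raised in all 6 treatments 570 were among the dimmest 20% of genes. Of the 684, 358 were not well above background on any control array. Those 358 could enter the tests only through a treated group, so the filter on dim probes may add to the pattern, which was not tested. The negative controls rose by at most 0.48 intensity units. Genes among the dimmest 20% that rose at least 2-fold in a treatment had median rises of 17.2 (880 genes in 150 mM salt) or more. The negative controls were read after background subtraction, so they could not exclude an additive background difference. A slide effect could not be excluded or shown: dim genes raised at least 2-fold in heat differed by -0.45 log2 between the heat array on one slide and the heat arrays on another, and control had a slide of its own. A response to the treatments could not be shown either. Dim genes raised at least 2-fold in 300 mM salt were 0.91 log2 higher at 300 than at 150 mM salt. They were chosen by their values at 300 mM, which favours such a difference, and each dose had its own slide. The second dimmest spike-in probe read 1.28 log2 in control, and 2.45 and 3.45 in 150 and 300 mM salt. It read 3.78 and 3.69 in 200 and 400 mM mannitol, 2.96 in heat and 2.7 in combined stress. Its RNA was added in a fixed amount, so a response of the plants cannot account for these rises. They argue for a lower reading of the dimmest signal on the control arrays, shown for only 2 of 10 spike-in probes. How much of the gene pattern has that origin was not measured.

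Departures of combined stress from the sum of its parts of at least 2-fold were falls in 92.2% of cases. Under other scalings and background correction the share lay between 54.9% (quantile normalization) and 99.1% (authors' table), so the choice of scaling may account for it. In the brighter 60% of genes 76.2% were falls (95% interval 71.1 to 80.8), which left open whether dim control values contributed. Of the falls in the brighter 60% of genes, 27.4% had risen at least 2-fold in 2 or more single stresses, against 0.8% of all genes there. The single stresses are subtracted in the departure, and the same control arrays enter both values. A higher share was therefore built in and could not test whether responses add up. Responses that do not add up stayed possible.

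Salicylate genes stood above control in both mannitol groups and below it in heat. The lowest mannitol median over all scalings was 0.72 log2, and 0.81 over members well above background on every array, so neither scaling nor dim signal explains the pattern. On the slide with arrays of both groups all 21 members were higher in 400 mM mannitol than in heat (2 and 2 arrays, median 2.49 log2), which excludes a slide effect for that difference. A response to the treatments is consistent with these values, while the level of control, on its own slide, was not tested in this way.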

How the results depend on the processing

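Signal over background limits the dim genes, and 3 arrays per group limit precision. The cause was not tested for the changes below, except that a stricter threshold or fewer arrays passes fewer genes. Of 290 pairs of named gene and comparison in the text, 249 kept direction and call with normexp, 289 with quantile normalization, 288 with the authors' table, and 290 with median scaling, reference gene scaling, the mean of the probes and the replicate block. With arrays left out 1812 of 1830 values did. Normexp turned 5 falls of dim genes, to 0.41 (PME38), 0.60 (RBE) and 0.51 (LCR41) in 150 mM salt and to 0.79 (DIR5) and 0.85 (M17) in 400 mM mannitol, none passing.

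Genes changed with normexp background correction were 7577 for 300 mM salt against control (13173 in the main setting), 1533 for 150 mM salt (4042), 3194 for 200 mM mannitol (8300), 10007 for heat (15197), 4047 between the salt doses (8617), 1278 for 150 mM salt against 200 mM mannitol (5041), 3040 for combined stress against heat (6221), 9531 against 200 mM mannitol (14329) and 1269 for the departure (5108). The authors' table gave 2336 for 150 mM salt, 1039 between the mannitol doses (4291), 3313 for 150 mM salt against 200 mM mannitol, 5595 for 300 mM salt against 400 mM mannitol (8542) and 3650 for combined stress against heat. Array weights, whose estimation did not fully converge, gave 6759 for 150 mM salt, 8689 between the mannitol doses, 10744 for combined stress against heat and 7879 for the departure. Only the 6 arrays compared gave 2727 between the mannitol doses and 2831 for combined stress against heat.

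Asking for a 2-fold change as well left 3074 genes for 300 mM salt, 1297 for 150 mM salt, 2940 for 400 mM mannitol, 2151 for 200 mM mannitol, 4036 for heat and 4184 for combined stress against control. It left 1115 between the salt doses, 328 between the mannitol doses, 1413 and 1516 for salt against mannitol at the lower and higher doses, 986, 2103 and 2925 for combined stress against heat, 150 mM salt and 200 mM mannitol, and 2370 departures. With the fit limited to genes well above background on every array in addition, these were 1697, 612, 1630, 965, 2699, 2899, 461, 222, 593, 876, 741, 1602, 2084 and 1309, in the same order. An adjusted p under 0.01 left 2087 for 150 mM salt, 5120 for 200 mM mannitol, 4923 between the salt doses, 2052 between the mannitol doses, 2625 and 5451 for salt against mannitol, 3770 for combined stress against heat and 2706 departures.

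Leaving out 1 array at a time gave 2669 (without 150 mM salt replicate 3) to 3304 for 150 mM salt, 5419 (without 200 mM mannitol replicate 1) to 7864 for 200 mM mannitol, 2441 (without 400 mM replicate 3) to 4577 between the mannitol doses, and 3262 (without 200 mM mannitol replicate 1) to 4415 for 150 mM salt against 200 mM mannitol. Slide as a fixed block left 920 genes between the mannitol doses, 2991 for combined stress against heat and 4266 against 200 mM mannitol, and within 1 slide 1 and 0 passed for the former 2. As a random block slide had a correlation of -0.096.

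Shared responses numbered 1836 in the main setting, 491 with normexp, 689 at least 2-fold, 227 at least 2-fold in a fit of the genes well above background on every array, and 1409 to 2425 under other scalings. Replicate numbers did not pair the groups in general, although 150 mM salt and 400 mM mannitol had same-numbered correlations of 0.219, 0.315 and 0.133, the only 1 of 21 group pairs with all over 0.1. In all, 13 of 63 correlations of same-numbered arrays were over 0.1 (range -0.277 to 0.315, mean -0.008 against 0.004 for others), and with the replicate number as a block 13091 genes passed for 300 mM salt, 3844 for 150 mM salt, 15112 for heat and 4896 as departures. Of 198 list calls 0 passed with an estimated correlation, 182 with fry, 179 with normexp, 179 with quantile normalization, 162 with the authors' table and 196 with the replicate block.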

Other observations

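Lists not described so far moved too. In 400 mM mannitol 11 of 16 unfolded protein response genes rose (11 adjusted over the list alone, adjusted p = 0.000857, and adjusted p = 0.537 with an estimated correlation), and 7 of 9 ABA receptor genes fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.00222, and adjusted p = 0.416 with an estimated correlation). Light-harvesting genes rose in 15 of 18 cases in heat and fell in 2 without a camera call. In combined stress 12 of 16 unfolded protein response genes rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 9.25e-05, and adjusted p = 0.487 with an estimated correlation), and 12 of 15 senescence genes rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.00904, and adjusted p = 0.546 with an estimated correlation).

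The comparisons were set beside other splits of the same arrays. Each comparison of 3 and 3 arrays has only 10 splits, too few to exclude chance, and the real split ranked 1 in each. The highest counts of the other splits were 3 for 300 mM and for 150 mM salt (13173 and 4042 real), 0 and 1 for 400 and 200 mM mannitol (11519 and 8300), 2 for heat (15197), 1 for combined stress (15473), 1 between the salt doses (8617), 87 between the mannitol doses (4291), 3 and 0 for salt against mannitol (5041 and 8542), and 100, 1 and 0 for combined stress against heat, 150 mM salt and 200 mM mannitol (6221, 13046 and 14329). Departures numbered 5108 against at most 4157 in the other splits (rank 1 of 100), and shared responses 1836 against 0 (rank 1 of 100). These splits mixed arrays of groups that differ strongly, so they could test only whether the groups differ at all. They could not test whether changes add up, or what the common control arrays give to the shared calls. Chance was not excluded for the number of list calls, 198 against at most 217, with 6 of 100 splits as high.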
